A study of Rattus norvegicus with 16 samples.

How the data were processed

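RNA sequencing was done on hippocampus and hypothalamus of male Sprague Dawley rats, untreated or given fructose for 6 weeks, with 4 samples per group and tissue in the labels. Per the labels' protocols, poly-A RNA was enriched from total RNA, and libraries were sequenced on an Illumina instrument, with CASAVA 1.8.2 named for base calling. The deposited FPKM values come from a workflow in which the submitters' processing notes name TopHat, Bowtie, Cufflinks, Cuffdiff, TopHat2, Bowtie2 and the genome build rn5, without versions and in the same words for all samples. Each table pairs a locus identifier with a gene symbol and gives, for each library, the FPKM and a status flag. Locus identifiers differ between the tables, so the tissues were joined by symbol. The hippocampus table holds 18087 loci for 16223 symbols, of which 1743 have several loci, and the one for hypothalamus 17762 loci for 16183 symbols, of which 1472 have several. Values with a status other than OK were found for 117 loci in hippocampus (105 of them tested) and 36 in hypothalamus (28 tested), and these loci were kept.

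Samples were grouped by the labels' tissue and treatment, and columns were matched to samples by tissue, group and replicate number. The design fixed before the data were examined assumed 4 against 4 libraries in each tissue. The hypothalamus table holds 7 libraries, with no column for fructose replicate 4, so that comparison was made with 4 against 3. All 15 libraries of the tables were used. The tables hold FPKM and no read counts, so no count model was fitted and the depth is unknown. Ratios of very low FPKM values fall in steps when reads are few: against control replicate 2, 17% to 25.4% of such ratios in hippocampus and 26.8% to 35.1% in hypothalamus fell in a single bin for replicates 2 to 4, which gives depths of 0.934 to 1.47 and 0.975 to 1.11 relative to that library. For the replicate 1 libraries the share was 2.25% to 2.89%, so their relative depth could not be read in this way.

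The test, the gene lists, the named genes and the alternatives other than those named below as added were chosen before the data were examined. The list test of the difference between tissues, with its alternatives, and the adjustment over a single list were not part of the fixed design. An adjustment over a single list does not account for the number of lists tested. For each tissue, loci with a mean FPKM of at least 1 were tested (11385 in hippocampus, 11498 in hypothalamus) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using its moderated test with a trend in the prior variance, the group as the only term and Benjamini-Hochberg adjustment at 0.05. The difference between the tissues was tested as an interaction over the 8239 symbols with 1 locus in each table and tested in both. The 41 gene lists (21 of pathways, 20 of cell types and regions) were tested with camera at its preset inter-gene correlation of 0.01 where at least 5 members were tested, adjusted over all lists of the tissue; a list member with several loci was taken at the tested locus with the highest mean. camera with an estimated correlation and fry were alternatives. The estimated correlation was 0.67 for the extracellular matrix list and 0.78 for the meningeal fibroblast list in hippocampus, and 0.59 for the matrix list in hypothalamus. These lie far above the preset of 0.01, so the preset p-values of such lists overstate the evidence. They are to be read beside those with an estimated correlation. Printed errors are SD for FPKM values and SE of the model for log2 fold changes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

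The genes named in the text follow a rule. It takes up to 10 genes per direction past the threshold whose groups do not overlap, filled to 10 with the smallest unadjusted p among genes whose groups do not overlap. It adds up to 4 members with the smallest p of each list described, the 5 smallest p in each direction for the difference between tissues, and a fixed set (Bgn, Fmod, Khk, Slc2a5, Insr and Bdnf, and in hypothalamus Agrp, Npy, Pomc, Cartpt and Hcrt). Bgn and Fmod were in the fixed set because the study's paper names them. Symbols that are only placeholders were passed over. Genes named outside the rule are marked as chosen after their values were seen.

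The replicate numbers come from the labels, which do not say what a number stands for. Deviations from the group means of same-numbered control and fructose libraries had correlations of 0.89, 0.21, 0.48 and 0.41 for hippocampus replicates 1 to 4 and 0.85, 0.49 and 0.46 for hypothalamus replicates 1 to 3, all over 0.1, so the numbers were treated as pairing the samples and a fit with the replicate number as a block was set beside the group-only fit. Much of this comes from replicate 1: over replicates 2 to 4 alone the values were -0.23, 0.4 and 0.088 in hippocampus and 0.27 and 0.036 in hypothalamus. Some of these lie under 0.1, so pairing beyond replicate 1 is not shown and the block fit is read as an alternative only.

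The method was tested on simulated data with the real means, spread and replicate 1 shift and 100 loci changed by each of 2 sizes. In hippocampus, over 11260 loci, 67% of loci changed 2-fold and 92% of those changed 4-fold were recovered, with 3 unchanged loci called. In hypothalamus, over 11418 loci, the shares were 45% and 86%, with 1 unchanged locus called. These values are those of the group-only fit. With a batch term for replicate 1 the shares were 80% and 97% in hippocampus and 81% and 96% in hypothalamus. Unchanged loci called were then 6 and 3. The group-only fit of the main test thus missed more of the changed loci. The 2 changed lists were called in each tissue. Noise was drawn for each locus on its own, without correlation between genes. The simulation therefore does not test the calls of lists whose genes vary together. Changed loci had control means above 2 on log2(FPKM + 1), so the recovery of lower loci was not tested.

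Alternatives were other pseudocounts (0.1 and 0.01), no filter or a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, limma without the trend, with robust priors or with array weights, an adjusted p of 0.10, all libraries in one model, the replicate block, and leaving out each library in turn. Added after seeing the data were leaving out both replicate 1 libraries, a batch term for them, leaving out loci with a status other than OK, and joining the tissues by the locus with the highest mean. For neighbours of 1 gene, gene order was taken from a RefSeq table of the assembly GRCr8, with symbols matched to the tables and no coordinates used, since the files use rn5.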

Results

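Messenger RNA was measured by sequencing in the hippocampus and the hypothalamus of male Sprague Dawley rats that were untreated or given fructose for 6 weeks. The labels list 16 samples, with 4 untreated and 4 fructose samples for each tissue. The deposited tables hold 15 libraries, because the hypothalamus table has no column for fructose replicate 4. Hippocampus was compared as 4 against 4 libraries and hypothalamus as 4 control against 3 fructose libraries. The hippocampus table gives FPKM (a length- and depth-scaled measure of expression) for 18087 loci and the hypothalamus table for 17762. Read counts are not in these tables, so the depth of each library is unknown. The FPKM values of a library added up to 353703 to 402099 in hippocampus and 435105 to 492778 in hypothalamus. The labels do not say whether each sample is a separate rat, or whether the tissues came from the same rats, so the p-values measure only the spread between samples.

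The replicate 1 libraries of both groups stood apart in each tissue. In hippocampus their log2 values had r = 0.985 with each other across loci and r = 0.84 to 0.896 with the other libraries, which had r = 0.934 to 0.979 among themselves. In hypothalamus the same values were 0.98, 0.88 to 0.909 and 0.956 to 0.979. Each group holds 1 of these libraries per tissue.

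**Figure D1:**
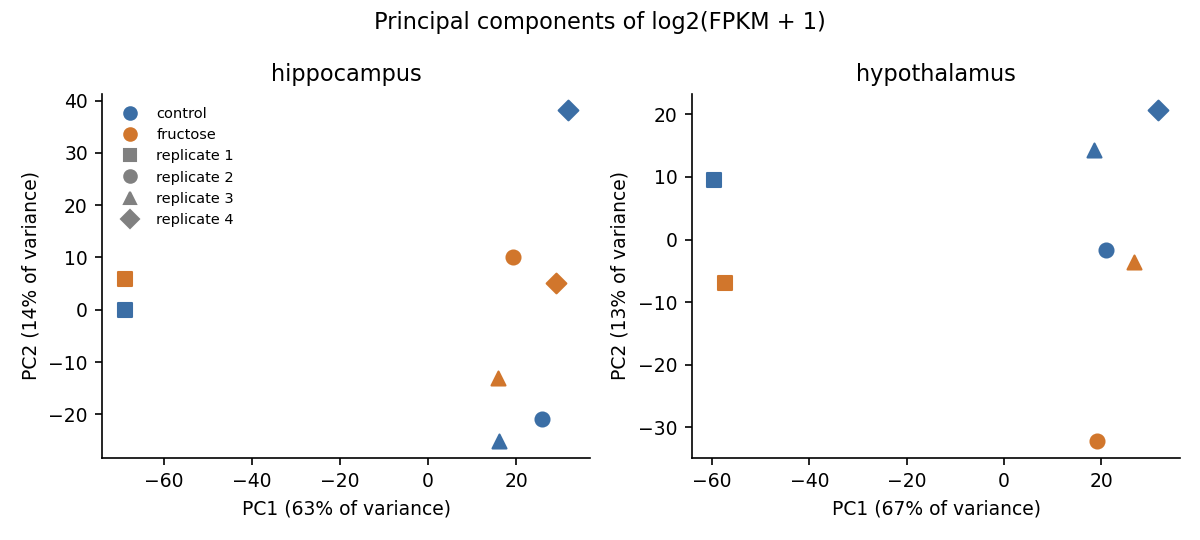
Principal components of the log2(FPKM + 1) values of the tested loci, with 1 point per library and axes in component units. Colour gives the group and shape the replicate number; the first component, with 62.9% of the variance in hippocampus and 66.8% in hypothalamus, parts the replicate 1 libraries (squares) from the others.

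The hippocampus comparison asked which transcripts differ after fructose in a region that serves memory. The transcripts that parted the groups most clearly included S100a9, a calcium-binding protein of inflammatory cells, and Rpl30, a protein of the large ribosomal subunit, although no gene passed the test. S100a9 was at 0.738 ± 0.503 FPKM (SD, n = 4) in control and 2.61 ± 0.945 FPKM in fructose samples, a log2 fold change of 1.06 ± 0.24 (SE). Rpl30 was at 14.8 ± 5.25 FPKM in control and 2.49 ± 2.80 FPKM in fructose samples, a log2 fold change of -2.38 ± 0.47. Eif5b, a translation initiation factor, was at 2.52 ± 2.12 and 0.1964 ± 0.06365 FPKM, and Msi1, an RNA-binding protein of neural progenitors, at 13.4 ± 1.31 and 9.62 ± 1.20 FPKM.

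Among the other genes with fructose values all above the control values were Xdh, the xanthine dehydrogenase of purine breakdown (1.09 ± 0.295 to 1.81 ± 0.178 FPKM), and Kctd16, an auxiliary subunit of GABA-B receptors (4.12 ± 0.672 to 5.53 ± 0.341 FPKM). The palmitoyltransferase Zdhhc2 (17.1 ± 1.71 to 21.1 ± 1.30 FPKM) and Lsp1, an actin-binding protein of leukocytes (2.04 ± 0.103 to 3.55 ± 1.39 FPKM), belonged to this group too. So did Lrrc33, Adam1a, Rps4y2, Gpr77 and Tmtc4, and the log2 fold changes of these 9 genes lay between 0.29 and 0.55. Fructose values all below the control values were found for the glutamate transporter Slc1a6 (3.09 ± 0.402 to 1.81 ± 0.549 FPKM), the cyclic GMP phosphodiesterase Pde9a (13.6 ± 1.27 to 10.1 ± 1.51 FPKM) and Chga, a protein of secretory granules (38.6 ± 6.94 to 26.4 ± 5.13 FPKM). Gbas, Nudt1, Arsj and Btbd16 were lower in the same way, with log2 fold changes between -0.46 and -0.29. Of these genes, Lrrc33, Adam1a, Rps4y2, Slc1a6, Arsj, Chga and Btbd16 have 2 loci in the table and their values are uncertain, since reads could be split between the loci.

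Of 11385 loci tested with limma, 0 passed an adjusted p of 0.05, and 92 had an unadjusted p under 0.05 (38 higher, 54 lower) where chance alone would give 569. That number was 203 with the replicate number as a block and 151 without both replicate 1 libraries. The groups did not overlap for 29 higher and 47 lower loci, which is 0.668% of those tested where chance gives 2.86%. Without control replicate 3, 1 gene passed, a locus of the ribosomal protein Rps9 that is 1 of 2 with this symbol (log2 fold change -2.76, limma adjusted p = 0.00221); it was chosen after its values were seen.

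As groups, the genes of the extracellular matrix and the markers of meningeal fibroblasts, the cells of the membranes around the brain, were higher in the hippocampus of fructose samples. All 34 tested matrix genes had a positive log2 fold change, with a median of 0.47 (camera adjusted p = 4.32e-14; adjusted p = 0.659 with an estimated correlation). Examples were the collagen Col1a1 (25.97 ± 22.4 to 83.7 ± 71.5 FPKM) and the proteoglycan Prelp (29.03 ± 9.34 to 40.4 ± 10.1 FPKM). Of the proteoglycans Bgn and Fmod, Bgn was at 29.7 ± 21.5 and 45.8 ± 16.3 FPKM and Fmod at 12.4 ± 8.39 and 21.3 ± 8.69 FPKM, the latter uncertain since it has 2 loci in this table. All 12 meningeal markers were positive too, with a median of 0.92 (camera adjusted p = 2.43e-08; adjusted p = 0.659 with an estimated correlation). They included the organic anion transporter Slc22a6 (5.51 ± 5.73 to 12.9 ± 6.69 FPKM), the GABA transporter Slc6a13 (6.27 ± 6.53 to 14.4 ± 9.24 FPKM) and Aldh1a2, an enzyme of retinoic acid synthesis (10.8 ± 12.9 to 21.4 ± 13.8 FPKM). Of 14 antigen presentation genes, 12 were positive, with a median of 0.43 (camera adjusted p = 5.04e-05; adjusted p = 0.659 with an estimated correlation). Among them were the class II genes RT1-Da (11.5 ± 10.3 to 24.95 ± 11.7 FPKM) and Cd74 (50.4 ± 42.7 to 102.3 ± 52.1 FPKM). The size depended on single libraries: the matrix median was 0.277, 0.275, 0.785 and 0.216 without control replicate 2, 3 or 4 or fructose replicate 2, the meningeal median was 0.475 and 0.541 without control replicate 3 or fructose replicate 2, and with array weights they were 0.936 and 1.691. The antigen presentation median was 0.133 without the filter on low values and 0.896 at a mean FPKM of at least 5. An RT1 locus can also differ strongly between single samples. RT1-CE16, outside the list and chosen after its values were seen, was at 22424 and 5040 FPKM in hypothalamus control replicates 1 and 3. It was at 0 in the other hypothalamus libraries. In hippocampus the same replicate numbers were highest, at 5.70 and 2.47 FPKM in control replicates 1 and 3. The other hippocampus libraries were at 0 to 0.29 FPKM. Whether equal numbers stand for the same rats, or the rats differ at this locus, was not tested. Whether such differences bear on the antigen presentation list was not tested. No member of the 3 lists passed, either over all genes (0) or adjusted over the list alone (0).

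Genes of energy and protein production were lower by small amounts in the fructose hippocampus, though not in every setting. Of 66 oxidative phosphorylation genes, 52 had a negative log2 fold change, with a median of -0.085 (camera adjusted p = 0.000524; adjusted p = 0.689 with an estimated correlation). They included the complex I subunit Ndufa10 (37.6 ± 2.18 to 30.7 ± 3.81 FPKM) and the cytochrome oxidase subunit Cox7b (96.2 ± 22.5 to 71.4 ± 13.3 FPKM). Without control replicate 1 the adjusted p was 0.401, and without fructose replicate 4 it was 0.669, with a median of 0.016. The median was -0.136, -0.16 and -0.147 without control replicate 2 or fructose replicate 2 or 3, and 0.008 with array weights (adjusted p = 0.434). Of 63 ribosomal protein genes, 46 were negative, with a median of -0.071 (camera adjusted p = 0.00223; adjusted p = 0.697 with an estimated correlation). Rps23 was at 65.3 ± 15.95 and 44.4 ± 11.3 FPKM. In control libraries the median level of these ribosomal genes was 23.1 FPKM, only 2.08 times that of all tested loci. Reads shared with gene copies may affect the whole list, which was not tested. For this list the adjusted p was 0.733 without control replicate 1, 0.0691 without control replicate 4 and 0.621 without fructose replicate 4. The median was 0.022 and 0.029 without the first and the last of these, and -0.155, -0.145 and -0.133 without control replicate 2 or fructose replicate 2 or 3. With array weights the direction turned and the list passed as higher (median 0.114, adjusted p = 0.0266). Of 23 genes of the unfolded protein response, 20 were positive, with a median of 0.052 (camera adjusted p = 0.00177; adjusted p = 0.659 with an estimated correlation). They included the disulfide isomerase Pdia4 (16.05 ± 2.03 to 20.3 ± 3.46 FPKM) and Herpud1 (28.4 ± 6.84 to 35.7 ± 4.82 FPKM). This call was lost without control replicate 1 (adjusted p = 0.265, median 0.01) or fructose replicate 4 (adjusted p = 0.0912), and the median was 0.106, 0.089 and 0.1 without control replicate 2 or 4 or fructose replicate 1. In all, 11 of 37 lists passed camera with its preset correlation, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 with fry (0 at an unadjusted p under 0.05). Without fructose replicate 4 there were 6. Without both replicate 1 libraries 6 of the 11 were lost: the unfolded protein (adjusted p = 0.0505, median 0.05), oxidative phosphorylation (0.394, -0.041), ribosomal (0.79, 0.026), endothelial (0.0932, 0.144), mural (0.0804, 0.249) and Ammon's horn (0.126, 0.142) lists. The unfolded protein, endothelial and Ammon's horn medians were about as large as with all libraries (0.052, 0.139 and 0.128). The choroid plexus list (12 of 14 positive, adjusted p = 0.278) and the inflammation list (12 of 17 positive, adjusted p = 0.0677) passed when the replicate number was a block, with an adjusted p of 0.0134 and 0.0373.

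The hypothalamus comparison asked the same question in the region that governs feeding and energy balance. Slc39a12, a zinc transporter of the ZIP family, was the 1 gene that rose. It was at 1.13 ± 0.221 FPKM (SD, n = 4) in control and 8.99 ± 0.675 FPKM (n = 3) in fructose samples. On log2(FPKM + 1) the log2 fold change was 2.23 ± 0.13 (SE, limma adjusted p = 0.00382). This is 4.7-fold for FPKM + 1, which is less than the ratio of the FPKM means. All 3 fructose libraries lay above all 4 control libraries. No gene fell past the threshold. Without fructose replicate 2 or 3 the limma adjusted p of Slc39a12 was 0.0589 and 0.0587, at log2 fold changes of 2.19 and 2.23. In a model of all libraries of both tissues it was 0.594. With the replicate number as a block 2 genes passed, Slc39a12 and a locus of the aminopeptidase Rnpep that is 1 of 2 with this symbol (log2 fold change 5.13, limma adjusted p = 0.00252). Rnpep also passed without control replicate 4 (limma adjusted p = 0.0258), and LOC685322 passed as higher without control replicate 3 (0.0102). A locus of Fbxw11, 1 of 2 with this symbol, passed as lower without control replicate 1 (log2 fold change -2.34, limma adjusted p = 0.0129). It also passed as lower without both replicate 1 libraries (limma adjusted p = 0.0467). These 3 genes were chosen after their values were seen.

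**Figure D2:**
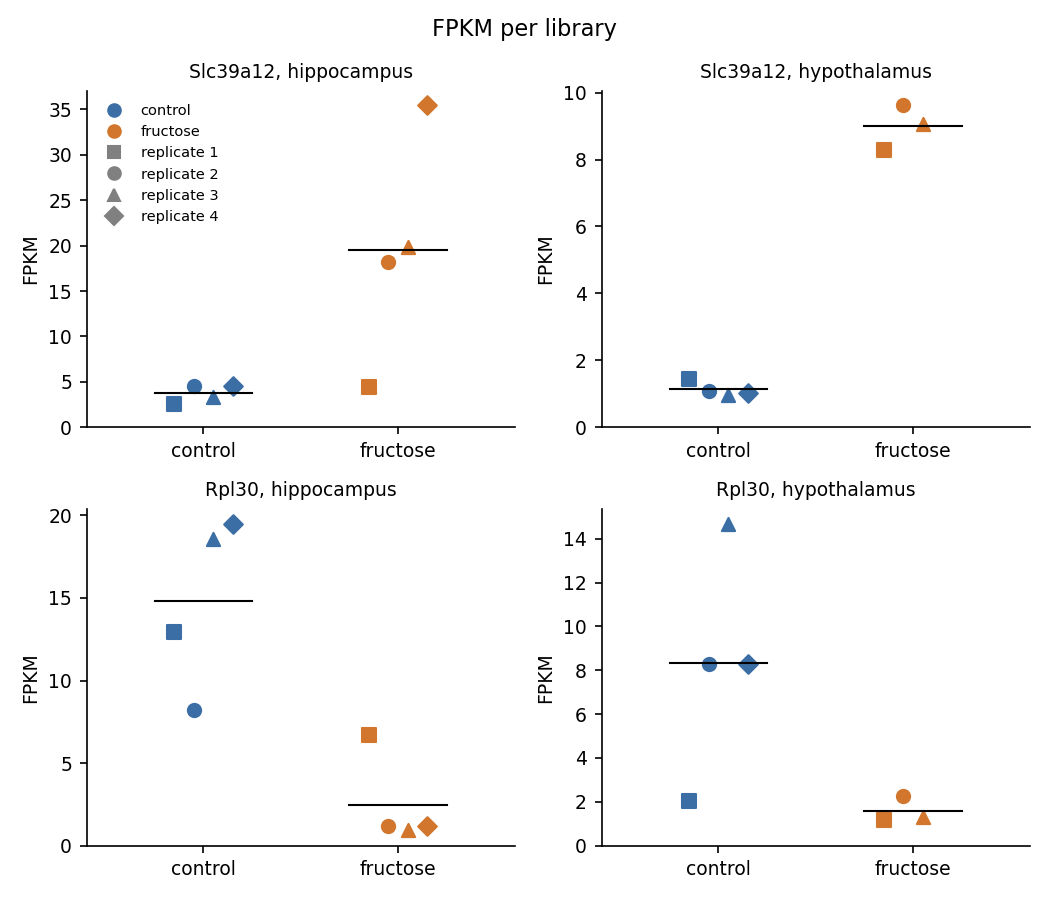
FPKM of Slc39a12 (upper panels) and Rpl30 (lower panels) per library in hippocampus and hypothalamus, with 1 point per library, shape for the replicate number and a bar at the group mean. In hypothalamus the fructose libraries lie at 8.28, 9.63 and 9.05 FPKM of Slc39a12 and the control libraries between 0.964 and 1.45; in hippocampus fructose replicate 1, at 4.45, overlaps the control libraries, at 2.53 to 4.51.

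Several genes had higher values in all fructose libraries of the hypothalamus without passing the test. Of the ependymal and motile cilia list, the adenylate kinase Ak7 was at 3.79 ± 0.478 FPKM in control and 6.57 ± 0.327 FPKM in fructose samples, Ccdc153 at 8.43 ± 1.38 and 14.8 ± 1.71 FPKM. Outside that list, the dynein light intermediate chain Dnali1 was at 4.23 ± 0.671 and 7.44 ± 1.64 FPKM and Spata18 at 2.115 ± 0.783 and 5.46 ± 1.36 FPKM. Bbox1, the last enzyme of carnitine synthesis (2.41 ± 0.118 to 4.22 ± 0.501 FPKM), and the mitochondrial alanine aminotransferase Gpt2 (10.4 ± 1.04 to 15.2 ± 0.439 FPKM) were higher in the same way. So were Cables1, Crkl and Stoml3, with log2 fold changes between 0.54 and 0.69. Lower values in all fructose libraries were found for the calcium-binding protein S100a6 (21.4 ± 5.82 to 6.23 ± 2.18 FPKM), the NF-kappa-B inhibitor Nfkbia (35.3 ± 2.04 to 19.4 ± 3.40 FPKM), the cholesterol 25-hydroxylase Ch25h (9.66 ± 2.47 to 2.43 ± 1.58 FPKM) and the endothelial transcription factor Klf2 (35.3 ± 3.38 to 22.4 ± 3.36 FPKM). The cell cycle inhibitor Cdkn1c was lower at both of its loci (582.4 ± 176 to 152.9 ± 61.7 FPKM, and 15.5 ± 4.98 to 6.18 ± 1.12 FPKM). So were Igfbp6, Crabp2, Icam2 and Ccl19, with log2 fold changes between -1.72 and -0.48. Cables1, Cdkn1c and Icam2 have 2 loci in the table and their values are uncertain. Of 11498 loci tested, 361 had an unadjusted p under 0.05 (117 higher, 244 lower) where chance alone would give 575. It exceeded that number in other fits, with 759 (262 higher, 497 lower) with the replicate number as a block, 886 (394 higher, 492 lower) with a batch term for replicate 1 and 1077 (545 higher, 532 lower) without both replicate 1 libraries. The groups did not overlap for 201 higher and 182 lower loci, 3.33% of those tested where chance gives 5.71%.

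The meningeal and matrix lists were lower in the hypothalamus of fructose samples, the opposite of their direction in hippocampus. Of 13 meningeal markers, 12 had a negative log2 fold change, with a median of -1.61 (camera adjusted p = 8.12e-17; adjusted p = 0.319 with an estimated correlation). Examples were the retinoic acid binding protein Crabp2 (18.1 ± 3.96 to 5.37 ± 3.39 FPKM), the proline transporter Slc6a20 (55.3 ± 10.3 to 17.1 ± 10.6 FPKM) and Wnt6 (6.99 ± 1.91 to 2.20 ± 1.67 FPKM). Adjusted over the list alone 11 of the 13 markers passed (lowest adjusted p = 0.0237), while 0 passed over all genes. Of 34 matrix genes, 31 were negative, with a median of -0.52 (camera adjusted p = 4.22e-16; adjusted p = 0.35 with an estimated correlation). They included the proteoglycan Lum (13.2 ± 1.46 to 6.30 ± 2.50 FPKM) and Fbln1, a protein of elastic fibres (64.1 ± 14.4 to 34.1 ± 16.95 FPKM). Adjusted over the list alone 0 passed, and 0 over all genes; with the replicate number as a block 16 of the 34 passed over the list alone. Markers of mural cells, the contractile cells of vessel walls, had a median of -0.84 with 8 of 11 negative (camera adjusted p = 1.63e-05; adjusted p = 0.319 with an estimated correlation). They included vitronectin, Vtn (81.5 ± 19.2 to 45.1 ± 10.6 FPKM), and Tagln (187.7 ± 76.4 to 83.4 ± 50.01 FPKM), with 0 of 11 adjusted over the list alone (7 with the block) and 0 over all genes. The mural list was lost without both replicate 1 libraries (adjusted p = 0.0537, median -0.905). Without fructose replicate 2 the meningeal median was -0.907 and the matrix median -0.334. Of 12 endothelial markers 9 were negative, with a median of -0.23 (camera adjusted p = 0.0018; adjusted p = 0.319 with an estimated correlation; adjusted p = 0.325 without fructose replicate 1). Among these the receptor Kdr was at 5.64 ± 1.08 and 3.84 ± 0.516 FPKM.

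As groups, glucocorticoid-responsive and inflammation genes were lower in the hypothalamus of fructose samples, and markers of ciliated ependymal cells, which line the ventricles, were higher. Of 20 glucocorticoid-responsive genes 16 were negative, with a median of -0.20 (camera adjusted p = 0.000704; adjusted p = 0.319 with an estimated correlation). They included the phosphatase Dusp1 (24.7 ± 3.35 to 14.2 ± 5.70 FPKM), while Zbtb16, a transcription factor of the same list, was higher (4.03 ± 1.23 to 6.57 ± 0.459 FPKM). Of 18 inflammation genes 15 were negative, with a median of -0.27 (camera adjusted p = 0.000522; adjusted p = 0.35 with an estimated correlation; adjusted p = 0.335 without fructose replicate 1). Nfkbia, a member of both lists, was the 1 gene that passed adjusted over the list alone in each (adjusted p = 0.00943 and 0.00848), with 0 over all genes. The glucocorticoid median was -0.13 and -0.106 without fructose replicate 1 or 2, and the inflammation median -0.166 without fructose replicate 2. With quantile normalization these medians were -0.124 and -0.146, and that of the immediate early genes -0.012. With the replicate number as a block 4 glucocorticoid-responsive and 3 inflammation genes passed adjusted over the list alone. Of 22 immediate early genes 14 were negative, with a median of -0.10 (camera adjusted p = 0.00278; adjusted p = 0.445 with an estimated correlation). They included Klf4 (12.4 ± 1.19 to 8.39 ± 1.20 FPKM) and Fos (36.1 ± 5.34 to 27.02 ± 5.24 FPKM). This call was lost without fructose replicate 1 (adjusted p = 0.511, median 0.001) or fructose replicate 3 (adjusted p = 0.0634, median -0.037). The median was -0.175 and -0.188 without control replicate 2 or fructose replicate 2, and 0.076 with array weights (adjusted p = 0.9). Of 11 ependymal markers 10 were positive, with a median of 0.55 (camera adjusted p = 2.12e-09; adjusted p = 0.319 with an estimated correlation). Besides Ak7 and Ccdc153 these included Spag6 (5.10 ± 0.996 to 8.03 ± 1.16 FPKM) and Tmem212 (9.69 ± 2.64 to 15.5 ± 1.09 FPKM). The ependymal median was 0.36 without both replicate 1 libraries. Adjusted over the list alone 3 of the 11 passed (lowest adjusted p = 0.00994; 6 of the 11 with the block), with 0 over all genes.

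Genes of inhibitory transmission and of lipid synthesis were higher by smaller amounts in the hypothalamus of fructose samples. Of 22 GABA synapse genes 18 were positive, with a median of 0.16 (camera adjusted p = 0.00136; adjusted p = 0.35 with an estimated correlation). They included the receptor subunit Gabbr2 (52.9 ± 9.50 to 67.7 ± 7.06 FPKM) and the GABA transaminase Abat (116.9 ± 11.8 to 163.9 ± 44.7 FPKM). The median was 0.098 and 0.105 without fructose replicate 1 or 2. Of 15 genes of fatty acid and triglyceride synthesis 10 were positive, with a median of 0.18 (camera adjusted p = 0.0164; adjusted p = 0.319 with an estimated correlation). They included the desaturases Fads2 (126.6 ± 9.91 to 177.7 ± 35.1 FPKM) and Scd1 (5.13 ± 0.954 to 8.83 ± 3.25 FPKM). This call was lost without control replicate 1 (adjusted p = 0.0758), control replicate 3 (0.0521, median 0.105), fructose replicate 2 (0.144, median 0.031) or fructose replicate 3 (0.0634). In all, 18 of 40 lists passed camera with its preset correlation, 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 0 with fry (2 at an unadjusted p under 0.05). Without control replicate 1 there were 10 and without fructose replicate 3 there were 11. Without both replicate 1 libraries 9 of the 18 were lost: the mural list (adjusted p = 0.0537, median -0.905) and those of immediate early (0.505, -0.02), inflammation (0.386, -0.146), antigen presentation (0.34, -0.525), interferon (0.606, 0.021), endothelial (0.219, -0.136), thalamus and habenula (0.34, 0.18), striatum (0.0689, 0.141) and red blood cell (0.147, -0.418) genes. Of these the immediate early, inflammation, interferon and endothelial medians were smaller by over 1.5 times than with all libraries, and the other 5 were not. The oxidative phosphorylation list (42 of 69 negative, adjusted p = 0.0908) passed when the replicate number was a block (adjusted p = 0.019), with a batch term for replicate 1 (0.0377) and without both replicate 1 libraries (6.91e-05).

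**Figure D3:**
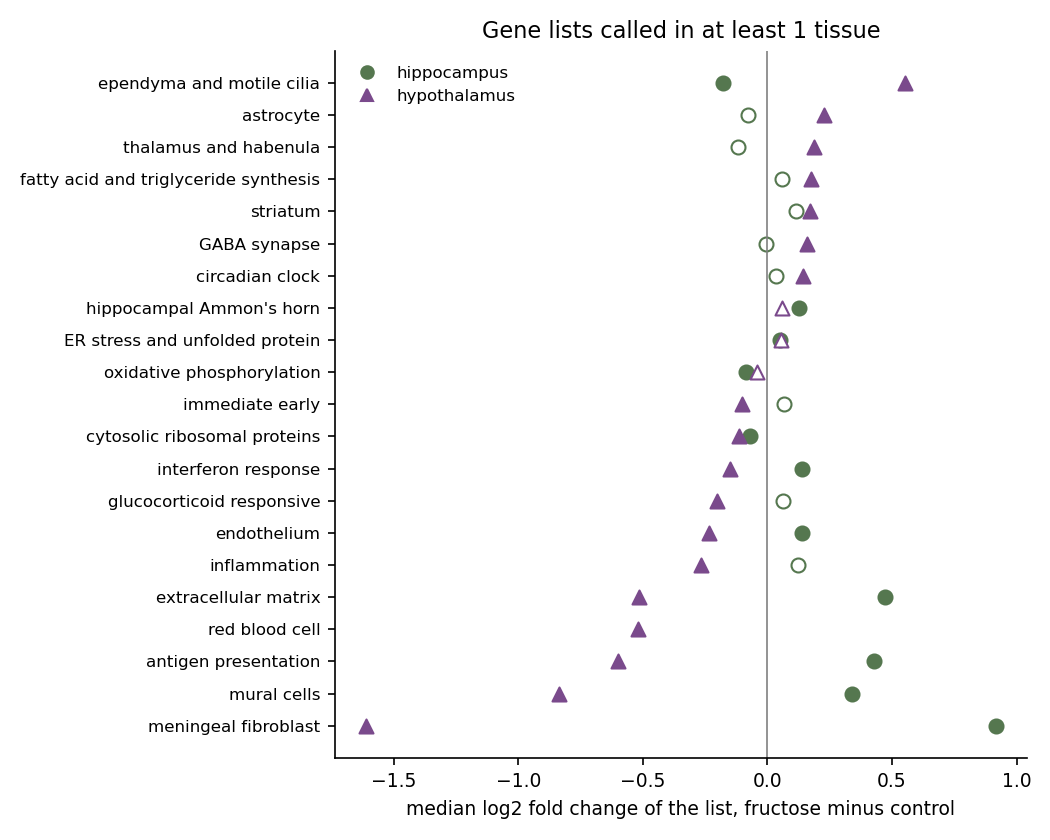
Median log2 fold change of each gene list that passed camera with its preset correlation in at least 1 tissue, fructose minus control, with circles for hippocampus and triangles for hypothalamus. Filled symbols passed an adjusted p of 0.05 and open symbols did not; the meningeal list lies at 0.92 in hippocampus and -1.61 in hypothalamus.

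Genes of fructose handling, insulin signalling and feeding were followed in both tissues whatever their result. Slc2a5, the fructose transporter GLUT5, was at 4.35 ± 0.974 FPKM in control and 6.60 ± 0.68 FPKM in fructose hypothalamus (log2 fold change 0.52 ± 0.17, limma adjusted p = 1), with all fructose values above the control values. It was at 2.98 ± 0.497 and 3.41 ± 0.474 FPKM in hippocampus. Khk, the ketohexokinase that starts fructose breakdown, was at 3.82 ± 1.12 and 3.28 ± 0.939 FPKM in hippocampus and was not analysed here in hypothalamus. The fructose catabolism list was not called in either tissue (median -0.003 with 4 of 9 positive in hippocampus, camera adjusted p = 0.845; median -0.075 with 3 of 8 positive in hypothalamus, camera adjusted p = 0.824). The insulin receptor Insr was at 6.40 ± 1.47 and 6.62 ± 0.401 FPKM in hippocampus, where it has 2 loci, and 4.67 ± 0.678 and 4.94 ± 0.668 FPKM in hypothalamus. The growth factor Bdnf was at 10.4 ± 2.47 and 11.4 ± 3.74 FPKM in hippocampus and 5.31 ± 1.31 and 5.50 ± 1.85 FPKM in hypothalamus.

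No member of the insulin and leptin signalling list passed in hypothalamus, over all genes (0) or adjusted over the list alone (0). Among its smallest p-values, Igfbp2, which binds insulin-like growth factors, was at 183.7 ± 91.2 and 58.2 ± 47.9 FPKM. The growth factor Igf1 was at 7.72 ± 1.97 and 4.43 ± 1.66 FPKM, and the transcription factor Foxo1 at 6.97 ± 1.04 and 10.7 ± 2.61 FPKM. The list as a whole was not called (18 of 27 positive, camera adjusted p = 0.219), nor was it in hippocampus (15 of 25 positive, 0.341, but 0.0373 without fructose replicate 3). Among feeding neuropeptides of the hypothalamus, Pomc was at 154.9 ± 69.3 and 198.4 ± 36.6 FPKM, and Agrp at 19.01 ± 9.29 and 21.03 ± 7.76 FPKM. Cartpt was at 446 ± 140.7 and 520.2 ± 31.7 FPKM, Hcrt at 825.3 ± 267.6 and 582.8 ± 148.7 FPKM, and Pmch at 1247 ± 508.1 and 819.5 ± 319 FPKM. Npy had a mean of 0.0133 FPKM there, below the level tested. A low value of 1 locus need not mean low expression in these data. Gapdh, chosen after its values were seen, was at 4.88 to 7.14 FPKM in hippocampus and 420 to 746 FPKM in hypothalamus. Whether reads of Npy were assigned elsewhere was not tested. The feeding list was not called in hypothalamus (17 of 29 positive, camera adjusted p = 0.226, but 0.0376 without fructose replicate 2) or in hippocampus (10 of 17 positive, 0.89). The glutamatergic synapse list was not called in hippocampus (25 of 43 positive, camera adjusted p = 0.806), but it was higher without control replicate 2 (0.0337) and lower without control replicate 4 (0.023). In hypothalamus it was not called (28 of 40 positive, camera adjusted p = 0.0528), but was without control replicate 2 (0.0114), without both replicate 1 libraries (0.0368), with a batch term for them (0.0412), with array weights (0.00589) and without the filter on low values (0.0327).

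Bgn and Fmod are named in the study's paper and are not independent choices. In hypothalamus Bgn was at 74.4 ± 29.5 and 35.1 ± 22.7 FPKM (log2 fold change -1.16 ± 0.45, limma adjusted p = 1) and Fmod at 22.7 ± 6.37 and 13.3 ± 7.39 FPKM (-0.81 ± 0.34, limma adjusted p = 1). In hippocampus their log2 fold changes were 0.79 ± 0.44 and 0.88 ± 0.49.

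The last comparison asked whether the fructose change differs between the tissues, over 8239 genes tested in both. No gene differed past the threshold (0 in limma, with 209 at an unadjusted p under 0.05 where chance alone would give 412, and 0 with the replicate number as a block). The 5 smallest p-values in each direction belonged to Lrrc46, Spata18, Dnph1, Spag6 and Hsd17b14, for which the hypothalamus change minus the hippocampus change was 0.745 to 1.22, and to Slc28a2, Tbx18, Hspb2, Chst15 and Fam180a, for which it was -2.13 to -0.71. Without hypothalamus control replicate 3, 1 gene passed, and with array weights 339 did.

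By list the tissues differed for 13 of 34 lists with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.106). The difference in the median log2 fold change, hypothalamus minus hippocampus, was -2.52 for meningeal markers (camera adjusted p = 2.47e-17; adjusted p = 0.106 with an estimated correlation), -1.10 for matrix genes (5.03e-25; adjusted p = 0.143 with an estimated correlation), -1.43 for antigen presentation genes (1.69e-07; adjusted p = 0.143 with an estimated correlation) and 0.80 for ependymal markers (1.44e-09; adjusted p = 0.106 with an estimated correlation). With the replicate number as a block the monoamine and GABA synapse lists no longer differed (adjusted p = 0.2 and 0.173, against 0.0305 and 0.0422) and the choroid plexus list did (0.0472, against 0.268). Without hypothalamus control replicate 1 there were 8 such lists and without hypothalamus fructose replicate 1 there were 7. Of the 8 lists called in both tissues, 7 went opposite ways and 1, the ribosomal protein list, was lower in both; with array weights it was higher in hippocampus (adjusted p = 0.0266), and without both replicate 1 libraries its median there was 0.026. Across genes, which are not independent replicates, the fold changes of the tissues had a Spearman correlation of -0.005 and a Pearson correlation of -0.25. Over 100 draws with the group labels reassigned within each tissue these lay between -0.352 and 0.47 and between -0.4 and 0.599. Leaving out hippocampus fructose replicate 4 gave a Spearman correlation of -0.194.

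At an unadjusted p under 0.05 in each tissue, 2 genes were higher in both tissues, Slc39a12 and the prostaglandin receptor Ptger3, the latter chosen after its values were seen, where independent lists of 23 and 71 genes would share 0.2. Rpl30 was the 1 gene lower in both, where lists of 33 and 176 would share 0.7, so this overlap is near chance. Both expected numbers assume independent tissues, and the labels do not say whether the tissues came from the same rats. Slc39a12 in hippocampus, chosen after its values were seen, had a log2 fold change of 1.86 (limma adjusted p = 1), with fructose libraries at 4.45, 18.2, 19.8 and 35.45 FPKM and control libraries at 2.53, 4.51, 3.29 and 4.51 FPKM. Rpl30 in hypothalamus was at 8.32 ± 5.16 and 1.58 ± 0.608 FPKM, a log2 fold change of -1.66 ± 0.51.

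**Figure D4:**
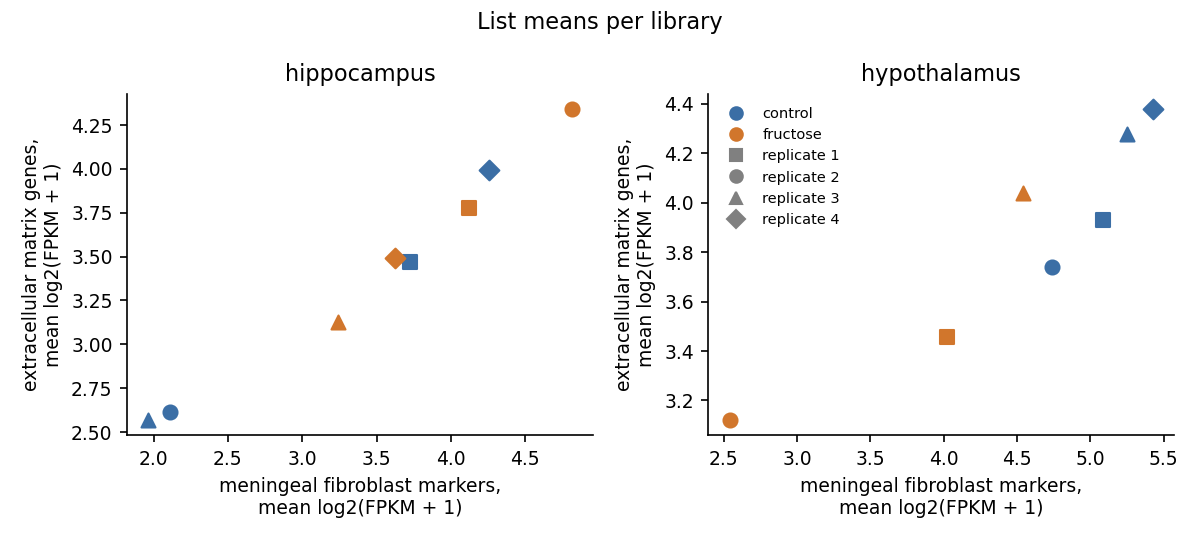
Mean log2(FPKM + 1) of the extracellular matrix genes (vertical axis) against that of the meningeal fibroblast markers (horizontal axis), with 1 point per library. Within groups the means had r = 0.99 in hippocampus and r = 0.87 in hypothalamus; the lowest meningeal means are those of hippocampus control replicates 2 and 3 and, in hypothalamus, of fructose replicate 2.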

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

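Among the tests below, those on leaving out the replicate 1 libraries, on the level of Rpl30 and on loci absent from replicate 1 were chosen only after the result was seen.

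Matrix and meningeal genes were lower with fructose in hypothalamus and higher in hippocampus. A different share of meningeal tissue in the dissected samples is a candidate explanation. Over all libraries, with terms for the group and for replicate 1 taken out, the mean of the 34 matrix genes followed that of the meningeal markers. The r was 0.94 in hypothalamus and 0.99 in hippocampus. With the meningeal mean as a covariate, the median log2 fold change of the matrix genes went from -0.516 to 0.075 and from 0.472 to -0.075. That of Bgn went from -1.16 to 0.02 and from 0.79 to 0.11, and that of Fmod from -0.81 to -0.07 and from 0.88 to 0.20. Within groups alone Pearson's r was 0.87 over 7 hypothalamus libraries (exact two-sided permutation p = 0.0417, adjusted over both tissues 0.0417; Spearman's rho 0.89, p = 0.0139, adjusted 0.0139; r = 0.76 without the 2 farthest libraries) and 0.99 over 8 hippocampus libraries (p = 0.00174, the smallest possible, adjusted 0.00348; rho 0.98, p = 0.00347, adjusted 0.00694; r = 0.98 without the 2 farthest). The most abundant marker in hypothalamus, Ptgds, chosen after its values were seen, was at 8401 ± 3055 FPKM in control and 2534 ± 2192 FPKM in fructose samples. The replicate 1 libraries are argued against as the cause, since without them the meningeal median kept at least 112% of its size in both tissues, and an effect of fructose on the meninges stays open and untested.

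Slc39a12 was higher and Rpl30 lower with fructose in both tissues at an unadjusted limma p under 0.05. Only Slc39a12 in hypothalamus passed the threshold. The overlap of 1 lower gene, Rpl30, is near the 0.7 that independent lists would share and may be chance. The replicate 1 libraries are argued against as the cause for Slc39a12, which kept at least 105% of its log2 fold change without them. A change over the whole chromosome region is argued against too, by the median of the neighbours of Slc39a12. Of its 10 nearest genes 8 were tested in each tissue, with a median log2 fold change of 0.007 in hippocampus and 0.079 in hypothalamus. The number higher at an unadjusted p under 0.05 was 0, but this count says little in hippocampus. There the highest neighbours, Vim (1.012) and Mrc1 (0.723), had an unadjusted limma p of 0.175 and 0.179. In hypothalamus these 2 genes were at -0.502 and -0.414, and the highest neighbour was Hacd1 (0.357). For Rpl30, reads shared with copies of the gene may explain part of the change and cannot be told apart from it, because Rpl30 was at 64.1% and 22.1% of the median ribosomal protein level in control libraries and that median itself, at 23.1 and 37.6 FPKM, was 2.08 and 3.13 times the median of all loci; the bound for this test was revised after its value was seen, since the first bound, 50% of the list median in either tissue, was passed at 64.1% and would have argued against shared reads. An effect of fructose and a variant in the gene itself that differs between the groups' rats stay open.

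The replicate 1 libraries of both groups stood apart in each tissue, and reads assigned to other loci of the same symbol, a test added once the next had come out, are a candidate explanation for part of it: 188 loci in hippocampus and 133 in hypothalamus were under 0.1 FPKM in replicate 1 and over 1 in all other libraries, 96.8% and 94.7% of them had another locus of the symbol present there, against 7.74% and 7.75% of other loci, and at most 1 locus was absent from replicate 2 or 3 alone. A shift in the same direction in both tissues is argued against for symbols with 1 locus, since the replicate 1 shifts of the tissues had a Spearman correlation of -0.45 across genes. Of the 11 genes shifted by over 1 in both tissues, though, 9 shifted the same way. For replicates 2 and 3 the correlation was -0.09 and -0.13, so the replicate 1 shifts are related, with opposite sign. A cause that moves the tissues in opposite directions is not covered by this test and stays open. A different dissection cannot be told apart from these, as the region lists that moved most, those of Ammon's horn in hippocampus and dentate gyrus in hypothalamus, had median shifts of -0.318 and 0.318, between the bounds set for and against it. Lists outside that test moved more, among them choroid plexus (1.114) and meningeal markers (0.591) in hippocampus and red blood cell (0.883) and heat shock genes (0.49), which mark no region, in hypothalamus, so the dissection stays open.

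Other splits of the libraries were tried to see whether chance can be excluded. For genes in hippocampus the real count was 0, which all 35 of 35 splits reach whatever they give (highest other 1), so the comparison says nothing there. In hypothalamus 9 of 35 splits gave at least the real 1, with at most 1 in another, so chance is not excluded. Splits with both replicate 1 libraries on one side also gave 1 gene in hypothalamus, where Slc39a12 had a limma adjusted p of 0.00194 with a batch term. For lists, 14 of 35 splits gave at least the real 11 in hippocampus (highest other 17) and 3 of 35 gave at least the real 18 in hypothalamus (highest other 20), and chance is not excluded there either. Splits with both replicate 1 libraries on one side gave up to 14 lists in hippocampus, where a batch term gave 11. Of the 8 splits that part as many pairs as the real one, 6 gave as many lists in hippocampus (highest other 16) and 1, the real one, in hypothalamus (highest other 13), and 3 gave as many genes in hypothalamus. At an unadjusted p under 0.05 other splits gave up to 1914 genes in hippocampus and 3274 in hypothalamus, against the real 92 and 361, which points to a structure of the samples. Both of these highest splits put the replicate 1 libraries on one side, unlike the real one. Among splits that part the replicate 1 libraries, the highest other gave 983 genes in hippocampus and 476 in hypothalamus. For the difference between tissues, the real count of 0 genes is reached by 100 of 100 splits whatever they give, which says nothing about chance, and the highest other, 431, points to a structure of the samples. For its lists 7 of 100 splits gave at least the real 13 (highest other 16), so chance is not excluded. The splits for the difference between tissues were drawn without regard to the replicate numbers, so the replicate 1 difference enters them.

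The fructose change differed between tissues by camera's test of the difference, with the preset correlation alone, for 13 lists. The hypothalamus minus hippocampus medians were -1.097 for extracellular matrix, -2.517 for meningeal fibroblasts, 0.801 for ependyma, -1.429 for antigen presentation, -0.337 for endothelium, -0.199 for the interferon response, -0.343 for inflammation, -0.263 for glucocorticoid-responsive genes, -0.453 for mural cells, -0.166 for immediate early genes, 0.315 for thalamus and habenula, 0.237 for monoamine genes and 0.2 for GABA synapse genes. Single libraries lay far from the other 3 of their group for 8 of 160 groups checked, and chance gives about 8. In hippocampus these were Bdnf in control replicate 2 (14.1 FPKM, others 8.99 to 9.42) and Rpl30 in fructose replicate 1 (6.69, others 0.921 to 1.19). In hypothalamus control samples they were Icam2 in replicate 4 (6.08, others 6.70 to 6.75), Spag6 in replicate 3 (6.59, others 4.48 to 4.73), Tmem212 in replicate 1 (5.74, others 10.7 to 11.3), Dusp1 in replicate 1 (19.7, others 26.1 to 26.7), Crh in replicate 2 (6.5, others 8.07 to 8.21) and Cry1 in replicate 1 (9.77, others 7.18 to 7.44).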

How the results depend on the processing

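The alternatives that leave out both replicate 1 libraries, add a batch term for them, leave out loci with a status other than OK or join the tissues by the locus with the highest mean were chosen only after the result was seen. No gene passed in hippocampus under any alternative (0 each) except when single libraries were left out (0 to 1). In hypothalamus the count was 1, but 0 at a mean FPKM of at least 5, where Slc39a12 was no longer tested, 0 with all libraries in one model, 2 with the replicate block, 2 with both replicate 1 libraries left out, and 0 to 2 with single libraries left out. For the difference between tissues it was 0, but 339 with array weights and 0 to 1 with single libraries left out. Lists numbered 11 in hippocampus, 18 in hypothalamus and 13 for the difference, 0 in each with an estimated correlation, 0 in each with fry, and 6 to 14, 10 to 19 and 7 to 14 with single libraries left out; at a mean FPKM of at least 5 the difference had 6. Without both replicate 1 libraries 5 of the 11 and 9 of the 18 lists kept their call and 3 were gained in each tissue: immediate early (adjusted p = 2.29e-05), oligodendrocyte (0.000397) and neocortex (0.0237) in hippocampus, oxidative phosphorylation (6.91e-05), glutamatergic synapse (0.0368) and oligodendrocyte precursor (0.0368) in hypothalamus. Leaving out any 1 library, 3 of the 11 (matrix, meningeal, antigen presentation) and 6 of the 18 (meningeal, matrix, mural, ependymal, GABA synapse, glucocorticoid) kept it throughout; of these, mural was lost without both replicate 1 libraries. Adjusted over the list alone, the replicate block also raised the hypothalamus members that passed from 11 to 12 for meningeal markers, from 0 to 2 for choroid plexus and from 0 to 1 for fructose catabolism, immediate early, ribosomal, endothelial and red blood cell genes. Besides these and those given beside the results it changed no other call. The Spearman correlation of -0.005 lay between -0.194 and 0.112 with single libraries left out.

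Some medians and log2 fold changes changed sign, and among the called lists 1 passed in the other direction. The hippocampus glutamatergic synapse list, not called with all libraries (median 0.019), passed as lower without control replicate 4 (median -0.108, camera adjusted p = 0.023). With array weights the changed values were 0.008 for the hippocampus oxidative phosphorylation list, 0.114 for its ribosomal list (adjusted p = 0.0266, called as higher), 0.076 for the hypothalamus immediate early list, -0.094 for Insr in hippocampus and -0.059 for Bdnf in hypothalamus. Without both replicate 1 libraries they were 0.026 for the hippocampus ribosomal list, 0.021 for the hypothalamus interferon list and -0.097 for Bdnf in hypothalamus, which was -0.083 with the replicate block and -0.011 with the batch term. With single libraries left out the ranges were -0.155 to 0.029 for the hippocampus ribosomal list, -0.16 to 0.016 for its oxidative phosphorylation list, -0.188 to 0.001 for the hypothalamus immediate early list, -0.089 to 0.145 for Insr and -0.07 to 0.306 for Bdnf in hippocampus, and in hypothalamus -0.049 to 0.477 for Agrp, -0.189 to 0.18 for Bdnf and -0.014 to 0.149 for Insr. Apart from the loss of Slc39a12 at the higher minimum, the cause of these changes was not tested. The depth is unknown, so what it limits is not known either.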

Other observations

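Further lists passed camera with the preset correlation in hippocampus, each losing its call without some single libraries and with an estimated correlation. Interferon response genes had a median of 0.139 with 16 of 20 positive (adjusted p = 0.00906; adjusted p = 0.689 with an estimated correlation), including the antiviral Bst2 (25.6 ± 13.4 to 34.8 ± 5.76 FPKM); without control replicate 2 or 3 or fructose replicate 2 or 4 the adjusted p was 0.796, 0.446, 0.299 and 0.0951. Endothelial markers had a median of 0.139 with 11 of 12 positive (adjusted p = 0.00932; adjusted p = 0.689 with an estimated correlation), including the clotting factor Vwf (11.5 ± 8 to 14.6 ± 4.28 FPKM); without control replicate 2 or 3 or fructose replicate 1 or 4 it was 0.288, 0.432, 0.181 and 0.0951. Mural markers had a median of 0.339 with 9 of 10 positive (adjusted p = 0.0108; adjusted p = 0.689 with an estimated correlation), including Cnn1 (3.41 ± 3.85 to 5.68 ± 3.79 FPKM); without control replicate 2 or 3 or fructose replicate 1 or 2 it was 0.361, 0.432, 0.194 and 0.299. Markers of Ammon's horn had a median of 0.128 with 7 of 9 positive (adjusted p = 0.0124; adjusted p = 0.659 with an estimated correlation), including Cpne4 (46.8 ± 14.1 to 63.05 ± 6.89 FPKM); without control replicate 1 or 4 or fructose replicate 3 or 4 it was 0.33, 0.203, 0.0707 and 0.0912. Ependymal markers, which were higher in hypothalamus, had a median of -0.18 with 9 of 11 negative (adjusted p = 0.00785; adjusted p = 0.659 with an estimated correlation), including Spag6 (4.31 ± 1.07 to 3.07 ± 1.53 FPKM); without control replicate 3 or fructose replicate 2 or 3 it was 0.115, 0.323 and 0.22.

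In hypothalamus the same holds for lists of other cell types and functions. Astrocyte markers had a median of 0.225 with 8 of 11 positive (adjusted p = 0.0201; adjusted p = 0.445 with an estimated correlation), including the glutamate transporter Slc1a2 (185.9 ± 58.7 to 266.8 ± 47.7 FPKM), while the connexin Gjb6 was lower (108.8 ± 15.9 to 82.2 ± 8.71 FPKM); without control replicate 3 or fructose replicate 2 or 3 the adjusted p was 0.0738, 0.495 and 0.0698. Circadian clock genes had a median of 0.144 with 13 of 18 positive (adjusted p = 0.0164; adjusted p = 0.383 with an estimated correlation), including Cry1 (7.94 ± 1.22 to 9.26 ± 0.318 FPKM); without control replicate 1 or fructose replicate 2 or 3 it was 0.133, 0.156 and 0.381. Antigen presentation genes had a median of -0.601 with 10 of 11 negative (adjusted p = 0.000704; adjusted p = 0.383 with an estimated correlation), including Cd74 (133 ± 5.16 to 88.7 ± 84.6 FPKM); without control replicate 1 or fructose replicate 2 it was 0.133 and 0.0943. Interferon genes had a median of -0.15 with 21 of 24 negative (adjusted p = 0.004; adjusted p = 0.544 with an estimated correlation), including Ifit3 (1.59 ± 1.14 to 0.494 ± 0.264 FPKM); without control replicate 1 or fructose replicate 1 or 2 it was 0.758, 0.325 and 0.0943. Ribosomal protein genes had a median of -0.114 with 44 of 64 negative (adjusted p = 0.00321; adjusted p = 0.445 with an estimated correlation), including Rps28 (1.93 ± 0.77 to 0.578 ± 0.0619 FPKM). Their median control level was 37.6 FPKM, only 3.13 times that of all tested loci, so reads shared with gene copies may affect this list too. Without control replicate 1 or fructose replicate 3 its adjusted p was 0.0758 and 0.602. Red blood cell genes, with 5 of 5 negative and a median of -0.519 (adjusted p = 0.0109; adjusted p = 0.486 with an estimated correlation), included Alas2 (21.6 ± 14.5 to 11.9 ± 4.34 FPKM); without control replicate 1 or 3 or fructose replicate 2 or 3 it was 0.252, 0.124, 0.0943 and 0.0959. Markers of striatum (median 0.169, 7 of 11 positive, adjusted p = 0.0265; adjusted p = 0.319 with an estimated correlation) and of thalamus and habenula (median 0.188, 12 of 13 positive, adjusted p = 0.0309; adjusted p = 0.486 with an estimated correlation) also passed. For striatum, with the dopamine receptor Drd1 (2.34 ± 0.575 to 3.24 ± 0.223 FPKM), the adjusted p was 0.208, 0.0589, 0.156 and 0.162 without control replicate 1 or 2 or fructose replicate 2 or 3. For thalamus and habenula, with Ramp3 (4.78 ± 1.95 to 6.52 ± 0.9 FPKM), it was 0.219, 0.0589, 0.0621, 0.0597 and 0.838 without control replicate 1, 2 or 3 or fructose replicate 1 or 2.

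Other settings also ended some of these calls. With array weights the adjusted p was 0.25 for Ammon's horn and 0.434 for oxidative phosphorylation in hippocampus, and 0.9 for immediate early, 0.107 for inflammation, 0.101 for interferon, 0.432 for endothelial and 0.0541 for striatum genes in hypothalamus. Without the filter on low values it was 0.0916 for Ammon's horn and 0.142 for striatum, and at a mean FPKM of at least 5 it was 0.271 for striatum and 0.0936 for thalamus and habenula, which had 0.051 and 0.0567 with pseudocounts of 0.1 and 0.01. With single libraries left out the medians of the lists above ranged in hippocampus from 0.027 to 0.232 for interferon, 0.091 to 0.335 for endothelium, 0.155 to 0.701 for mural cells, 0.071 to 0.242 for Ammon's horn and -0.352 to -0.088 for ependyma. In hypothalamus they ranged from 0.114 to 0.41 for astrocytes, 0.07 to 0.222 for the clock, -0.707 to -0.138 for antigen presentation, -0.26 to -0.023 for interferon, -0.245 to -0.033 for ribosomal, -0.841 to -0.297 for red blood cell, 0.067 to 0.161 for striatum and 0.05 to 0.323 for thalamus and habenula genes. Other settings moved some medians beyond these ranges. Without both replicate 1 libraries they were -0.496 for ependyma and 0.281 for interferon in hippocampus and 0.456 for astrocytes in hypothalamus. With array weights they were -0.584 for ependyma and 0.764 for mural cells in hippocampus, and 0.524 for astrocytes and 0.497 for thalamus and habenula in hypothalamus.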
